A study of Mus musculus with 17 samples.

How the data were processed

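Gene expression was measured by RNA sequencing of mouse kidney in 17 libraries. The labels place them in 3 groups, with 4 libraries labelled control (wild-type genotype), 6 labelled Ctr shRNA and 7 labelled Gcgr shRNA, a short hairpin RNA against the glucagon receptor gene that was meant for proximal tubule cells. Titles of both shRNA groups carry the abbreviation DKD, and the series concerns diabetic kidney disease. For the Ctr shRNA group the labels differ, as its titles say Vehicle and its genotype says Ctr shRNA, so whether these kidneys received a control hairpin or a vehicle alone is uncertain. How the disease was induced and how the shRNA was delivered are not given in the sources used here. Libraries are named by their group and the number in their title. The labels do not tie each library to its own animal, so p-values measure the spread between these samples.

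RNA was extracted with Trizol and libraries were made with a SMARTer mRNA-Seq kit, per the labels' protocols. The authors deposited a single table of FPKM (fragments per kilobase of gene, scaled by library size) per gene and library, with gene lengths and coordinates, per the file headers. The aligner, the counter, the annotation release and the use of strand are not given in the sources used here, and GRCm38 and mm10, names of one mouse genome build, are listed per the submitters' processing notes. Of 42767 gene IDs of the table found in a GRCm38 annotation, 41922 (98.0%) had the same chromosome, start and end. The table held 42794 complete gene lines, of which 31784 had a value above 0 in any library. It was sorted by falling mean, and 1 line at its end, among genes at 0, was incomplete and was left out. Reads of near-identical copies, such as members of the Cyp4a, Cyp2d, Ugt1a and H2 families, and of overlapping or antisense genes could be split in unknown ways, so their values are uncertain.

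Multiplied by gene length, the low FPKM values (up to 200 steps) were whole multiples of 1 step per library in 100% of cases, within a tolerance of 0.05 of a step. The reads recovered this way summed to 13997657 to 17107876 per library, with means of 15233480 in control, 16375751 in Ctr shRNA and 15823963 in the libraries labelled Gcgr shRNA. The library size that the authors divided by was 0.949 to 1.15 times that sum. Pairs of replicates differed by 6.61 to 68.9 times the sampling noise (chi-square over degrees of freedom), more than resequencing of a single preparation would give. This does not show that they come from separate animals, and each library was counted as 1 replicate.

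FPKM values as deposited were transformed to log2(FPKM + 1), a scale that understates the changes of low genes. Genes with an FPKM of 1 or more in at least 4 libraries were tested, 13279 in all. A linear model with a mean per group, fitted to all 3 groups, was tested with limma 3.58.1 (limma-trend) in R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gcgr was tested by an exact two-sided permutation test of the mean log2(FPKM + 1). For 42 gene lists of metabolic pathways, stress and immune responses and cell type markers (731 genes), limma's camera compared each list of at least 5 tested members (38 lists) with the other genes at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which tests whether a list moves one way, were run beside it. The count of members passing adjusted over the list alone is given beside the count adjusted over all genes.

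Genes are named by this rule. In each comparison Gcgr and Gcg are named, with the 10 largest changes in each direction among genes passing the threshold with a mean FPKM of at least 1 in the higher group, without predicted genes, clones, pseudogenes and receptor segments. Up to 4 members per list with the smallest p among those passing are added, or up to 2 where none passes. Where no gene passes, the 5 with the smallest p in each direction are given as values. Some genes that this rule picks are not reported here. The design, lists, rule and most alternatives were fixed before the data were examined. Chosen after seeing the data were limma voom on the recovered reads, leaving out both libraries that stand apart (Ctr shRNA 20 and Gcgr shRNA 31), the exact test of Gcgr between the libraries labelled Gcgr shRNA and control, a list of p53 target genes with and without members already named, a list of urothelial markers, the tests of Gcgr against the markers of 5 nephron segments, and the draws of unchanged groups for the split correlation. Alternatives covered the pseudocount, the filter, the scaling, the variance model, the groups in the fit, the list test and each library left out in turn.

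The steps were tested on simulated data drawn from the real genes' means and spread, with 100 genes changed per fold size. Changes of 1.5-fold and 2-fold were recovered in 47.5% and 78.8% of tested genes for Ctr shRNA against control, in 53.1% and 82.5% for Gcgr shRNA against Ctr shRNA, and in 58.6% and 80.0% for Gcgr shRNA against control. Comparisons sharing a group were set beside 100 simulated draws of unchanged groups. All 17 columns of per-sample values were used.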

Results

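RNA from mouse kidney was sequenced in 4 control libraries, 6 libraries labelled Ctr shRNA and 7 labelled Gcgr shRNA, to follow what glucagon signalling in proximal tubule cells does to renal lipid metabolism. Each library held 13997657 to 17107876 recovered reads, and 12183 to 12919 genes reached an FPKM of 1. The first principal component took 21.0% of the variance and the second 15.2%. The library Ctr shRNA 20 lay apart from the others on both, at 35.9 and 34.3, and held transcripts of fat and urothelium. Adipoq, a fat cell hormone, was at 45.3 FPKM there and at most 2.43 elsewhere, and Upk3a, a structural protein of the bladder lining, at 56.8 and at most 3.23.

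Gcgr, the glucagon receptor and the target of the hairpin (ENSMUSG00000025127, GRCm38 chromosome 11, 120530699 to 120538986), was not lowest in the libraries labelled Gcgr shRNA. Its level was 20.8 ± 2.42 FPKM in control (SD, n = 4), 9.74 ± 2.14 in Ctr shRNA (n = 6) and 13.02 ± 1.70 in the libraries labelled Gcgr shRNA (n = 7). Control libraries 37, 38, 39 and 41 gave 21.5, 18.3, 19.4 and 23.8 FPKM. Ctr shRNA libraries 1, 4, 6, 8, 19 and 20 gave 10.3, 10.6, 8.80, 11.1, 11.8 and 5.89 FPKM. The libraries labelled Gcgr shRNA 13, 15, 29, 31, 32, 34 and 35 gave 11.02, 11.4, 14.1, 11.7, 15.7, 13.2 and 14.0 FPKM. Against Ctr shRNA the libraries labelled Gcgr shRNA were higher by 0.40 on the log2(FPKM + 1) scale (exact permutation p = 0.00641), which goes against their label as whole-kidney RNA shows it. Against control, Gcgr fell by 1.04 in Ctr shRNA (exact permutation p = 0.00476, the smallest that 210 splits allow) and by 0.64 in the libraries labelled Gcgr shRNA (exact permutation p = 0.00303, the smallest that 330 splits allow). These values rest on 3330, 2524 and 3749 recovered reads in control, Ctr shRNA and the libraries labelled Gcgr shRNA. Markers of the thick ascending limb were also higher in the libraries labelled Gcgr shRNA than in Ctr shRNA. The mean of the thick ascending limb markers in log2(FPKM + 1) was 5.63 in control, 5.10 in Ctr shRNA and 5.48 in the libraries labelled Gcgr shRNA, and the difference between the shRNA groups of 0.38 had an exact permutation p of 0.0105. The same difference was 0.19 for intercalated cell markers (exact permutation p = 0.0833), 0.17 for distal convoluted tubule (0.152), 0.15 for proximal tubule (0.173) and -0.12 for principal cell markers (0.656). The sign of the last depends on Ctr shRNA 20. Without that library the median log2 fold change of principal cell markers between the shRNA groups was 0.073. Gcg, which encodes glucagon itself, was listed at 0 in all libraries except the one labelled Gcgr shRNA 13, where it was at 0.0828 FPKM from 2 reads.

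**Figure D1:**
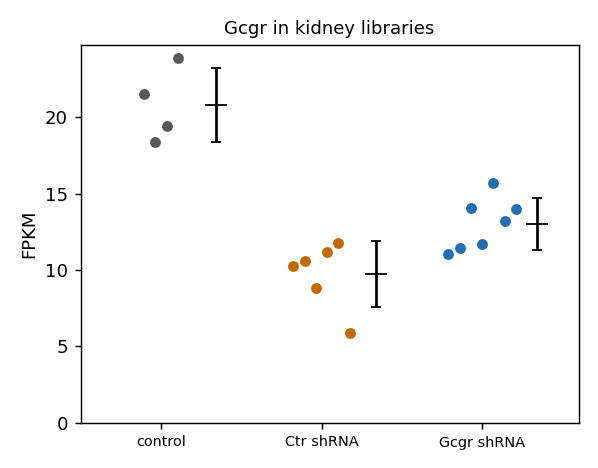
FPKM of Gcgr in each kidney library by group (points), with the mean and SD beside them (bars); the vertical axis is FPKM from 0. Control libraries lie between 18.3 and 23.8 FPKM, Ctr shRNA libraries between 5.89 and 11.8, and the libraries labelled Gcgr shRNA between 11.02 and 15.7.

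The first comparison set Ctr shRNA (n = 6) against control (n = 4), that is, the disease label together with a control hairpin, per the genotype label, against wild-type kidney. Folds here and in all comparisons are taken from means on the log2(FPKM + 1) scale and differ from ratios of the FPKM means, most of all for low genes. C3, the central component of complement, rose from 2.51 ± 0.467 to 40.8 ± 11.6 FPKM (SD), 11.5-fold on that scale. Cdkn1a, a cell cycle inhibitor induced by p53, rose from 2.29 ± 0.493 to 23.1 ± 4.41 FPKM, 7.27-fold on that scale, and Cxcl10, a chemokine induced by interferon, rose from 0.987 ± 0.179 to 7.57 ± 1.81 FPKM, 4.25-fold on that scale. Scd1, which makes monounsaturated fatty acids, fell from 54.2 ± 8.85 to 8.93 ± 2.97 FPKM. Cyp2d12, a cytochrome P450 gene, fell from 45.1 ± 3.35 to 6.59 ± 1.40 FPKM, and Cyp24a1, which breaks down active vitamin D, from 52.1 ± 45.0 to 9.28 ± 3.46 FPKM, with control libraries between 16.4 and 118 FPKM.

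Among genes passing limma's test in this comparison, the other large rises were those of Cyp4a14, a fatty acid omega-hydroxylase (log2 fold change 2.96 ± 0.46, SE, adjusted p = 0.00114), Lgals3bp (2.35 ± 0.23), Ugt1a10 (2.28 ± 0.33), Phlda3 (2.27 ± 0.20), Gdf15, a stress-induced cytokine (2.11 ± 0.27), Fgg, a fibrinogen chain (2.10 ± 0.58), and Ifi27 (2.07 ± 0.24). The other large falls were those of Slc22a7, an organic anion transporter (-2.08 ± 0.28, adjusted p = 0.000411), Hpd, of tyrosine breakdown (-2.05 ± 0.35), Azgp1 (-1.93 ± 0.28), Rnf24 (-1.69 ± 0.30), Car9 (-1.67 ± 0.25), Cyp2d9 (-1.56 ± 0.25) and Bcat1 (-1.50 ± 0.32). The call for Fgg ended without control 37, 38, 39 or 41 or Ctr shRNA 1, 4 or 8 (adjusted p up to 0.113). The genes in the plot of FPKM per library lie, on GRCm38, at chromosome 17, 57203970 to 57228136 (C3), chromosome 17, 29090976 to 29100727 (Cdkn1a), chromosome 5, 92346638 to 92348889 (Cxcl10), chromosome 15, 82555072 to 82560403 (Cyp2d12), chromosome 19, 44394451 to 44407709 (Scd1) and chromosome 2, 170482708 to 170497145 (Cyp24a1).

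Of 26 interferon response genes 20 rose in Ctr shRNA (26 adjusted over the list alone), among them Irf7, a regulator of interferon genes (3.65-fold), and Bst2, which tethers viruses (4.10-fold). For this list limma's camera gave an adjusted p = 2.04e-22, and adjusted p = 0.122 with an estimated correlation. Of 13 antigen presentation genes 12 rose (13 adjusted over the list alone), such as B2m (2.58-fold) and H2-D1 (1.94-fold), with an adjusted p = 1.07e-12 and adjusted p = 0.122 with an estimated correlation. Of 17 inflammation genes 9 rose (12 adjusted over the list alone), including C3, Cxcl10 and the adhesion molecule Icam1 (2.01-fold), with an adjusted p = 3.58e-12 and adjusted p = 0.111 with an estimated correlation. Of 27 tubular injury genes 7 rose (12 adjusted over the list alone), among them Vcam1 (1.64-fold) and Sox9 (1.58-fold, a call that ended without control 39 at adjusted p = 0.0720), with an adjusted p = 3.95e-08 and adjusted p = 0.215 with an estimated correlation. Of 14 macrophage markers 13 had a log2 fold change above 0 and 1 below (median 0.48). By limma's test 2 rose and 1 fell (7 and 1 adjusted over the list alone). Lyz2, a lysozyme, rose 2.46-fold and Csf1r, a growth factor receptor, fell by 0.95 on the log2 scale, and the list's adjusted p was 0.00104, with adjusted p = 0.359 with an estimated correlation. Of 4 tested T and natural killer cell markers, too few for camera, 1 rose over all genes, the chemokine Ccl5 (1.16 ± 0.26), and 4 adjusted over the list alone (median 0.70). Of 3 tested neutrophil markers 0 passed limma's test over all genes and 2 were lower adjusted over the list alone (median -1.12). Of 16 immediate early genes 5 rose (6 adjusted over the list alone), such as Btg2 (2.37-fold), and 3 without Ctr shRNA 20, at adjusted p = 0.00104 and adjusted p = 0.359 with an estimated correlation. Of 25 extracellular matrix genes 0 rose and 1, Col5a2, fell by limma's test (1 and 1 adjusted over the list alone), at an adjusted p of 0.386 for the list. The call for Col5a2 ended without control 38, 39 or 41 or Ctr shRNA 6 (adjusted p up to 0.0882).

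Part of the markers of 5 nephron segments fell in Ctr shRNA, and 0 of 10 podocyte markers passed limma's test. Of 22 proximal tubule markers 8 fell (13 adjusted over the list alone), among them Cyp2e1 (-1.12 ± 0.17, SE), Miox, of inositol breakdown (-0.79 ± 0.12), and Slc27a2, a fatty acid transporter (-0.68 ± 0.14), at adjusted p = 1.31e-08 by camera and adjusted p = 0.191 with an estimated correlation. Of 11 thick ascending limb markers 5 fell (7 adjusted over the list alone), such as Egf (-1.09 ± 0.20), at adjusted p = 4.62e-05 and adjusted p = 0.191 with an estimated correlation. Of 11 intercalated cell markers 6 fell (8 adjusted over the list alone), such as Insrr (-0.84 ± 0.13) and the proton pump subunit Atp6v1b1 (-0.79 ± 0.13), at adjusted p = 8.78e-08 and adjusted p = 0.122 with an estimated correlation. Of 11 distal convoluted tubule markers 3 fell (6 adjusted over the list alone), with Slc12a3, the thiazide-sensitive salt transporter, at -0.77 ± 0.14, and of 9 principal cell markers 4 fell (4 adjusted over the list alone), with the sodium channel subunits Scnn1b at -0.65 ± 0.09 and Scnn1g at -0.60 ± 0.10. Camera gave these 2 lists adjusted p-values of 7.92e-05 and 0.00261, and adjusted p = 0.20 and 0.171 with an estimated correlation. Of 20 amino acid and urea genes 7 fell (9 adjusted over the list alone), including Hpd, Kmo (-0.72 ± 0.11) and Gnmt (-0.94 ± 0.18), at adjusted p = 5.58e-05 and adjusted p = 0.215 with an estimated correlation. Of 12 genes known to be higher in male kidney 5 fell (7 adjusted over the list alone), at adjusted p = 1.49e-07 and adjusted p = 0.194 with an estimated correlation. With the library Ctr shRNA 20 left out, the counts passing were 6 for proximal tubule, 6 for thick ascending limb, 4 for intercalated cell and 2 for distal convoluted tubule markers.

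Of 21 cholesterol synthesis genes 7 fell in Ctr shRNA (10 adjusted over the list alone), such as Sc5d (-0.46 ± 0.07, SE), at adjusted p = 5.89e-06 and adjusted p = 0.111 with an estimated correlation. Of 25 lipogenesis and triglyceride synthesis genes 4 fell, and adjusted over the list alone 4 fell and 1 rose. They included Scd1 and the desaturases Fads1 (-0.76 ± 0.10) and Fads2 (-0.85 ± 0.14), and the list had an adjusted p = 0.0106 and adjusted p = 0.171 with an estimated correlation. Of 25 mitochondrial beta oxidation genes 1 rose and 2 fell (3 and 3 adjusted over the list alone), among them Acsm1, an acyl-CoA synthetase (-0.87 ± 0.13), and the list did not pass (adjusted p = 0.692). Of 26 peroxisomal and omega oxidation genes 2 rose and 3 fell (2 and 7 adjusted over the list alone; adjusted p = 0.275), with Cyp4a14 among the rises, and without Ctr shRNA 20 4 rose and 1 fell. Without that library 2 beta oxidation genes rose and 2 fell, and 1 lipogenesis gene rose and 6 fell. Of 14 genes of ketogenesis and its regulators 2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.541; median -0.03, mean 0.09, test direction down). Of 22 genes of lipid uptake, storage and lipolysis 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.343). Lipoprotein lipase, Lpl, fell to 0.452 times its control level, while the lipid droplet protein Plin3 rose 1.43-fold and the monoglyceride lipase Mgll rose 1.496-fold, the last call ending without control 38 (adjusted p = 0.0560) and after rescaling to the same total (adjusted p = 0.0785).

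In all, 994 of 13279 genes passed limma's test between Ctr shRNA and control, 475 higher and 519 lower, and 134 of them changed at least 2-fold. Over all 13279 genes the groups did not overlap in 1344, where chance gives 0.952% of genes. Of 38 lists, 19 passed with the preset correlation (9 up, 10 down), 0 with an estimated one and 16 with fry. The gene count was 487, 477, 456 and 659 without control 37, 38, 39 and Ctr shRNA 4, and 597 without a filter on low values and 2087 with sample weights.

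**Figure D2:**
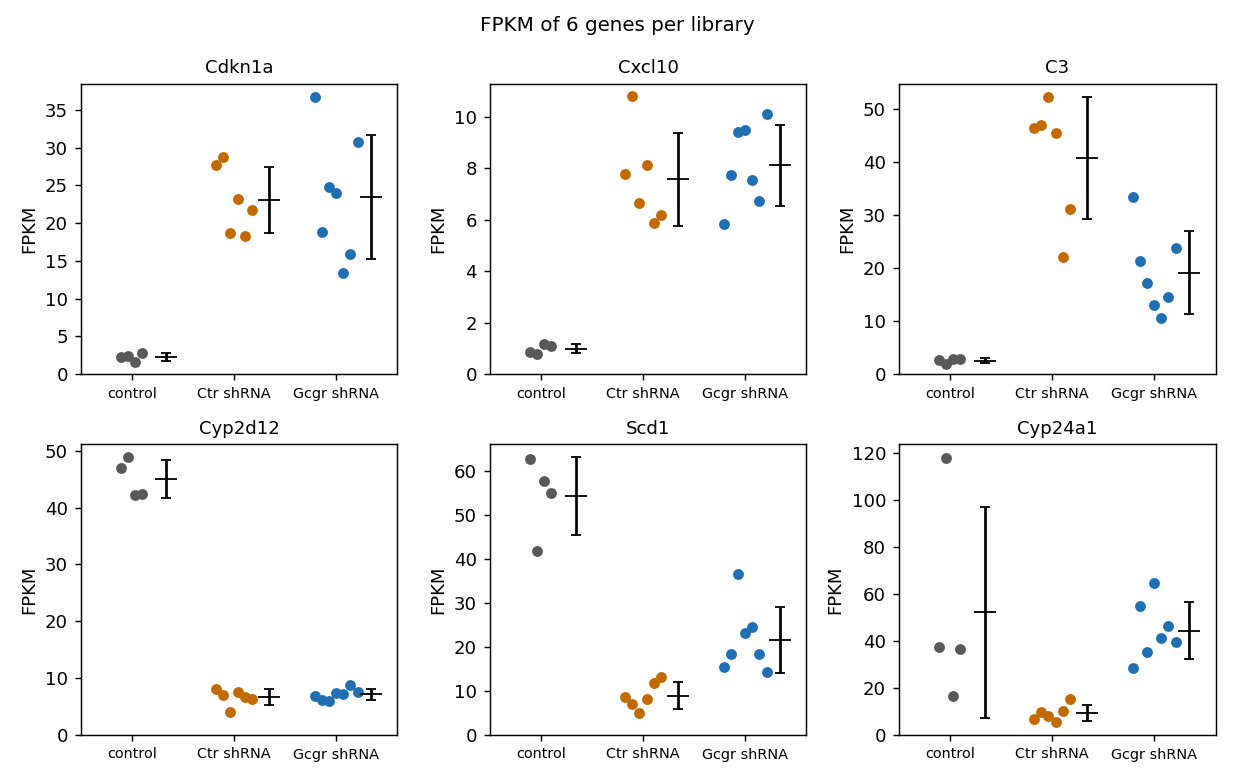
FPKM of 6 genes in each library (points) by group, with mean and SD (bars); each vertical axis is FPKM from 0. Cdkn1a, Cxcl10 and C3 are higher and Cyp2d12 and Scd1 lower in both shRNA groups than in control, and Cyp24a1 lies between 5.29 and 15.2 FPKM in Ctr shRNA and between 28.5 and 64.5 FPKM in the libraries labelled Gcgr shRNA.

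The second comparison, libraries labelled Gcgr shRNA (n = 7) against Ctr shRNA (n = 6), asks what the hairpin against Gcgr changed. Its direction is drawn between groups whose Gcgr level goes against the label. Cyp24a1 was at 44.3 ± 12.2 FPKM against 9.28 ± 3.46 (SD), 4.47-fold higher on the log2(FPKM + 1) scale, and missed the threshold at adjusted p = 0.0596. That fit shares 1 estimate of the spread with control, where this gene varied widely. With only the 2 shRNA groups fitted, limma gave it an adjusted p of 0.000946. On that scale Scd1 was 2.26-fold higher (21.5 ± 7.56 against 8.93 ± 2.97 FPKM), and the carboxypeptidase Cpe 1.89-fold (53.2 ± 5.24 against 29.1 ± 10.1 FPKM). Mgll was at 11.5 ± 2.05 against 18.1 ± 3.12 FPKM. These 3 genes had an adjusted p of 0.0911.

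Of 13279 genes 0 passed limma-trend, 972 had an unadjusted p under 0.05 where 664 would by chance (544 higher, 428 lower), and limma voom on the recovered reads called 1, Cyp24a1. The other genes with the smallest p were Mdk (log2 fold change 0.77 ± 0.14, SE), Zbtb22 (0.35 ± 0.07), Pbx4 (-0.59 ± 0.11), Snord37, a small nucleolar RNA (-1.36 ± 0.26), Dnajb13 (-0.83 ± 0.17) and Igf2bp2 (-0.41 ± 0.09), with adjusted p from 0.0911 to 0.156. Cyp24a1 also passed at a pseudocount of 0.1, at a mean FPKM of 5 or more, with only these 2 groups fitted, and without control 38, control 39, Ctr shRNA 20 or Gcgr shRNA 13, and its adjusted p ranged from 0.000946 to 0.209 over 30 alternatives. Mgll and Dnajb13 passed without Gcgr shRNA 13 (adjusted p = 0.0323 and 0.0120), and Ndrg2, named after its values were seen, without Ctr shRNA 20 (adjusted p = 0.0256; 28.9 against 21.4 FPKM).

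No list had a member passing over all genes. Of the 11 thick ascending limb markers 6 were higher adjusted over the list alone, with a median log2 fold change of 0.43, and Egf was at 0.53 ± 0.17 (SE). For this list camera gave adjusted p = 1.99e-07, and adjusted p = 0.218 with an estimated correlation. Of the 20 amino acid and urea genes 3 were higher adjusted over the list alone (median 0.19), with Kmo at 0.50 ± 0.10 and Gnmt at 0.79 ± 0.16, at adjusted p = 1.33e-07 and adjusted p = 0.218 with an estimated correlation. Distal convoluted tubule markers had a median of 0.18, with 11 of 11 above 0, and intercalated cell markers of 0.21, with 10 of 11 above 0. Without Ctr shRNA 20 the medians were 0.11 for amino acid and urea genes and 0.13 for intercalated cell markers. Camera gave the distal convoluted tubule and intercalated cell lists adjusted p-values of 0.00215 and 0.000814, and adjusted p = 0.615 and 0.514 with an estimated correlation. Proximal tubule markers had a median of 0.11 (0.055 without Ctr shRNA 20) and 1 of 22 higher adjusted over the list alone (adjusted p = 0.00574, and adjusted p = 0.749 with an estimated correlation). Cholesterol synthesis genes had a median of 0.09 and 0 of 21 passing adjusted over the list alone (adjusted p = 0.000621, and adjusted p = 0.218 with an estimated correlation). Genes of lipid uptake, storage and lipolysis had a median of -0.16, 1 of 22 lower adjusted over the list alone, and an adjusted p = 0.0107 (adjusted p = 0.218 with an estimated correlation). On this list Ctr shRNA 20, with its fat transcripts, was at 0.40 relative to the control mean, and other libraries at most at 0.18. Without Ctr shRNA 20 the median was -0.12, at adjusted p = 0.0310 by camera and adjusted p = 0.320 with an estimated correlation.

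Mitochondrial beta oxidation genes had a median of -0.02, with 0 of 25 passing over all genes or adjusted over the list alone (limma), and the list an adjusted p of 0.232. On this list Ctr shRNA 20 was at -0.35 relative to the control mean, the lowest of the 17 libraries. Without Ctr shRNA 20 the median was -0.10, at adjusted p = 0.00184 by camera and adjusted p = 0.656 with an estimated correlation. Lipogenesis genes had a median of 0.03 and 3 of 25 higher adjusted over the list alone (list adjusted p = 0.109, and 0.00668 without Ctr shRNA 20, where adjusted p = 0.303 with an estimated correlation). Interferon genes had a median of 0.014, a mean of -0.0013 and a test direction of up (adjusted p = 0.842). Without Ctr shRNA 20 the median was 0.12, at adjusted p = 0.00639 and adjusted p = 0.799 with an estimated correlation. Tubular injury genes had a median of -0.14 (adjusted p = 0.108; -0.035 and 0.980 without Ctr shRNA 20) and extracellular matrix genes of -0.23 (adjusted p = 0.0609; -0.11 and 0.63 without it). In all, 12 of 38 lists passed with the preset correlation (9 up, 3 down), and 0 with an estimated one or with fry. The balance of directions depends on Ctr shRNA 20. Without it, beta oxidation, peroxisomal and omega oxidation, gluconeogenesis, nuclear oxidative phosphorylation and antioxidant lists also passed as lower with the preset correlation. Lipogenesis and interferon lists also passed as higher. Calls for proximal tubule, endothelial, adipocyte, glucose and sodium transport and mitochondrially encoded genes ended without Ctr shRNA 20, at adjusted p = 0.152, 0.412, 0.458, 0.370 and 0.735. Without both Ctr shRNA 20 and Gcgr shRNA 31, 4 of the 12 calls remained, those of thick ascending limb, amino acid and urea, cholesterol synthesis and male-biased genes.

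The third comparison set the libraries labelled Gcgr shRNA (n = 7) against control (n = 4). Cdkn1a rose to 23.5 ± 8.26 FPKM (SD), C3 to 19.2 ± 7.81 FPKM and Cxcl10 to 8.12 ± 1.58 FPKM, which on the log2(FPKM + 1) scale is 7.14-fold, 5.44-fold and 4.55-fold. Cyp2d12 fell to 7.11 ± 0.968 FPKM, 0.175 times its control level on the log2(FPKM + 1) scale, and Scd1 to 21.5 ± 7.56 FPKM, 0.395 times. Cyp24a1 was at 44.3 ± 12.2 FPKM against 52.1 ± 45.0 FPKM (adjusted p = 0.938).

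The other large rises by limma were those of Phlda3 (log2 fold change 2.38 ± 0.19, SE), Gdf15 (2.20 ± 0.26), Lgals3bp (2.18 ± 0.22), Ifi27 (2.13 ± 0.24), Bst2 (2.08 ± 0.24), Irf7 (1.97 ± 0.23) and Cyp4a14 (1.90 ± 0.45). The other large falls were those of Rnf24 (-1.20 ± 0.30), Slc22a7 (-1.14 ± 0.28), Tmprss9 (-1.07 ± 0.12), Car9 (-1.03 ± 0.24), Cyp2d9 (-1.01 ± 0.24), the transcription factor Neurog2 (-1.01 ± 0.19), Hsd11b1, which regenerates active glucocorticoid (-0.99 ± 0.18), and Nxpe3 (-0.91 ± 0.17). Without control 37, 38 or 39 in turn the calls for Cyp4a14, Rnf24, Slc22a7, Car9 and Cyp2d9 ended (adjusted p up to 0.158), as they did without 2 to 8 further libraries each, and that for Nxpe3 ended without control 38 (adjusted p = 0.0506).

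Of the 26 interferon genes 18 rose (26 adjusted over the list alone), at adjusted p = 5.37e-32 and adjusted p = 0.070 with an estimated correlation. Antigen presentation genes rose in 11 of 13 (13 adjusted over the list alone), with B2m at 2.37-fold, and inflammation genes in 8 of 17 (13 adjusted over the list alone), with Icam1 at 1.84-fold, at adjusted p = 1.44e-18 and 4.09e-15 and both at adjusted p = 0.070 with an estimated correlation. Of 27 tubular injury genes 4 rose (5 adjusted over the list alone), at adjusted p = 7.63e-08 and adjusted p = 0.274 with an estimated correlation. Of 14 macrophage markers 2 rose, among them Lyz2 at 2.50-fold (9 higher and 1 lower adjusted over the list alone, and 2 rose and 1 fell without Ctr shRNA 20), at adjusted p = 3.37e-06 and adjusted p = 0.230 with an estimated correlation. Of 4 T and natural killer cell markers 1 rose over all genes, Ccl5 (1.12 ± 0.25, SE), and 4 adjusted over the list alone (median 0.71). The call for Ccl5 ended without any of the 4 control libraries or Gcgr shRNA 13 or 35 (adjusted p up to 0.107). Of 3 neutrophil markers 0 passed limma's test over all genes or the list alone (median -0.84). Of 22 proximal tubule markers 2 fell (4 adjusted over the list alone, and 4 over all genes without Ctr shRNA 20), with Miox at -0.64 ± 0.12 (SE), and of 9 principal cell markers 3 fell (3 adjusted over the list alone). Camera gave these 2 lists adjusted p-values of 1.68e-07 and 0.000133, and adjusted p = 0.230 and 0.0856 with an estimated correlation. Of 11 thick ascending limb markers 0 passed limma's test over all genes or the list alone (list adjusted p = 0.151). Of 21 cholesterol synthesis genes 1, Sc5d, fell by 0.37 on the log2 scale (2 adjusted over the list alone), and this call ended without control 38 (adjusted p = 0.0588). The list had an adjusted p = 0.00239 and adjusted p = 0.230 with an estimated correlation. Of 25 lipogenesis genes 2 fell (4 adjusted over the list alone; adjusted p = 0.0262 and adjusted p = 0.230 with an estimated correlation), and of 25 beta oxidation genes 1, Acsm1, fell (1 adjusted over the list alone, and 2 over all genes without Ctr shRNA 20; list adjusted p = 0.194). The call for Acsm1 ended without control 38, 39 or 41 (adjusted p up to 0.0677).

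Between the libraries labelled Gcgr shRNA and control 268 genes passed, 189 higher and 79 lower, and 64 changed at least 2-fold. The higher share was 70.5%, and 54.1% after rescaling every library to the same total. Over all 13279 genes the groups did not overlap in 735, where chance gives 0.606% of genes. Of 38 lists, 17 passed with the preset correlation, 0 with an estimated one and 11 with fry. The gene count was 131, 105, 103, 165 and 170 without control 37, 38, 39, Gcgr shRNA 13 and Gcgr shRNA 35, 155 without a filter on low values, 154 at a mean FPKM of 5 or more, 438 with only these 2 groups fitted and 1070 with sample weights.

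**Figure D3:**
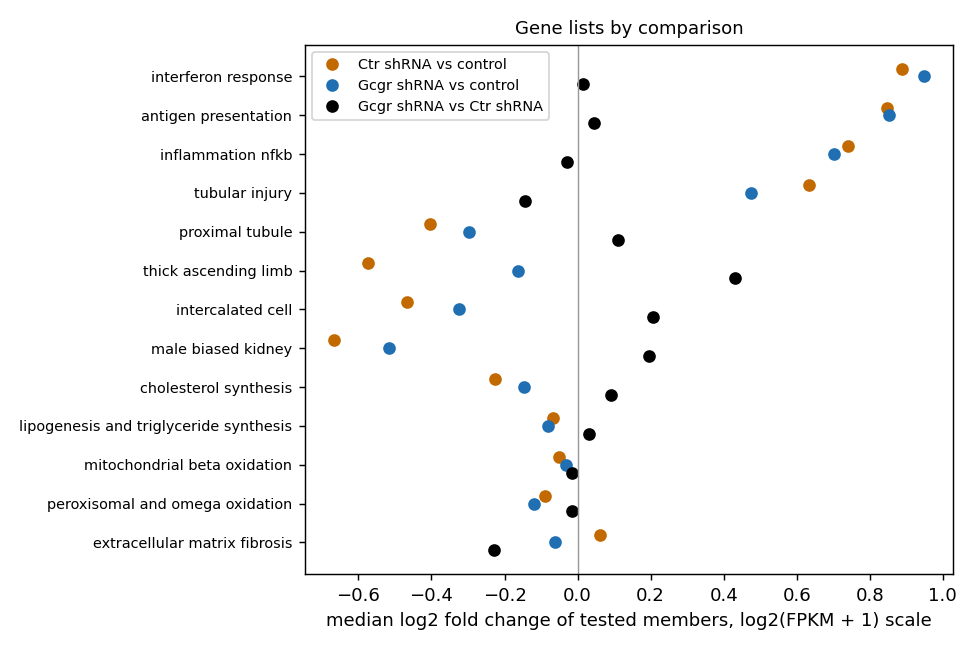
Median log2 fold change, on the log2(FPKM + 1) scale, of the tested members of 13 gene lists (vertical axis) in the 3 comparisons (colours). Interferon, antigen presentation and inflammation lists lie between 0.70 and 0.95 in both comparisons with control and between -0.03 and 0.04 between the shRNA groups, where without Ctr shRNA 20 the interferon and antigen presentation medians are 0.12 and 0.069.

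Both comparisons with control share the control libraries. They had 161 genes higher in both and 72 lower in both, and 0 in opposite directions. Independent lists of these sizes would share 6.76 and 3.09 genes. Simulated unchanged groups shared 0, but they had almost no calls to share. Per draw, means of 0.07 and 0.02 genes were called higher in the 2 comparisons, and 0.03 and 0.04 lower. Their 0 therefore does not measure the overlap that shared controls create. With the controls split into 2 and 2, the shared counts averaged 28.5 higher and 6.33 lower over 6 splits. These fits had fewer controls per comparison and called fewer genes. On average 109 and 36.2 genes were called higher in the 2 comparisons, and 107 and 8.17 lower. Independent lists of those sizes would share 0.284 and 0.0608 genes. The fall from 161 and 72 therefore does not measure the overlap that shared controls create. Fold changes correlated across genes, which are not independent replicates, at r = 0.824, against a mean of 0.599 in unchanged groups sharing the controls. The highest r in 100 draws of unchanged groups was 0.927, so the observed r lies within their range. The covariance of the fold changes was 0.0634, against a mean of 0.0191 (highest 0.0366) in unchanged groups. With split controls the 2 comparisons of the real groups share no library. Their mean r was then 0.585, from 0.556 to 0.624, and the mean covariance 0.0518. The unchanged groups share controls, so they are not the baseline for these split values.

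Whether the hairpin against Gcgr moved genes back toward control was examined by correlating the fold changes of Ctr shRNA against control with those of the libraries labelled Gcgr shRNA against Ctr shRNA. Across 13279 genes r was -0.551 and the covariance -0.0288. The shared Ctr shRNA libraries alone gave a mean r of -0.467 in 100 draws of unchanged groups, from -0.692 to -0.0952, and a mean covariance of -0.0134, at lowest -0.0254. With the Ctr shRNA libraries split into sets of 3, so that no library entered both comparisons, the mean over 20 splits was r = -0.197, from -0.366 to -0.0423, with a covariance of -0.0132. The same splits in 100 draws of unchanged groups gave a mean r of 0.00600, at lowest -0.249, with 8 draws as low as the observed, and a mean covariance of 0.000141, at lowest -0.0130, with 0 draws as low.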

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

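The splits of samples for the gene and list counts were set before the data were examined, except the split for genes between the 2 shRNA groups, and all other tests in this part were chosen after the result was seen. Chance is unlikely for the gene count of Ctr shRNA against control, where 1 of 100 splits, the real one, gave as many (994, highest other 514). The same holds for the libraries labelled Gcgr shRNA against control, where 1 of 100 did (268, highest other 17). This is the smallest share that 100 splits allow, and it takes each library as an independent sample. Chance cannot be excluded for the list counts, as 30 of 100 splits gave as many lists for Ctr shRNA against control (19, highest other 25), 59 between the shRNA groups (12, highest other 24) and 9 for the libraries labelled Gcgr shRNA against control (17, highest other 20). For genes between the shRNA groups the splits allow no test, since with a real count of 0 each of the 100 must give as many (highest other 4).

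Gcgr was higher, not lower, in the libraries labelled Gcgr shRNA than in Ctr shRNA, by 0.40 on the log2 scale (exact permutation p = 0.00641). The receptor is also expressed in the thick ascending limb, whose markers differed between the shRNA groups by nearly as much, 0.38. After subtracting the mean of these markers the difference was 0.024 (exact permutation p = 0.763), which follows from the closeness of those differences. It cannot tell a difference in tissue content from a change of expression within the same cells, so tissue content stays possible but undecided. Gcgr minus these markers still lay below control by 0.51 in Ctr shRNA and 0.48 in the libraries labelled Gcgr shRNA. Within Ctr shRNA, Gcgr and these markers correlated at r = 0.887 (exact permutation p = 0.00972, adjusted 0.0194; rank correlation 0.83, exact p = 0.0583), and at 0.878 without the 2 farthest libraries. Within the libraries labelled Gcgr shRNA r was 0.695 (exact permutation p = 0.0871, rank correlation 0.714, exact p = 0.0881), and 0.131 without the 2 farthest. Subtracting other segments' markers left 0.26 for proximal tubule (exact permutation p = 0.0192), 0.22 for intercalated cell (0.0932), 0.23 for distal convoluted tubule (0.255) and 0.52 for principal cell (0.00583). The r of these other segments with Gcgr ran from -0.730 to 0.872 within Ctr shRNA and from -0.559 to 0.707 within the libraries labelled Gcgr shRNA. These values include Ctr shRNA 20, which had the lowest Gcgr, and were not recomputed without it. Its principal cell markers were at 0.56 relative to the control mean, and those of the other Ctr shRNA libraries between -0.70 and -0.20. Without it the Gcgr difference itself was 0.28. An exchange of labels between the shRNA groups cannot be told from these data, since no measure independent of Gcgr marks the knockdown, and a knockdown confined to proximal tubule cells was not tested.

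The library Ctr shRNA 20 had 165 genes more than 1 log2 unit above every other library. Of 11 fat cell markers 11 were highest there, with a median gap of 3.31 log2 units to the next library, as were 11 of 12 urothelial markers, with a median gap of 3.01, so adhering fat and renal pelvis in the sample could account for it. Scaling does not, as the fat marker gap was 3.53 after rescaling to the same total. Only 5 fat and 7 urothelial markers entered the main test.

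Single values stood apart from their group by Dixon's test, at a rule by which chance picks about 1 group in 20; 13 of 237 groups had such a value. In the library labelled Gcgr shRNA 13 these were Cyp4a14 at 513 FPKM (next 219), Fgg at 76.9 (15.5), Plin3 at 18.3 (14.3) and Dnajb13 at 1.68 (0.726). In other libraries labelled Gcgr shRNA, Cyp2d9 was at 137 FPKM in 32 (next 92.2) and Ass1 at 861 in 31 (598). In Ctr shRNA, Neurog2 was at 1.45 FPKM in 19 (next 0.581), Ass1 at 657 in 19 (495) and Hsd11b1 at 23.5 in 6 (15.4). In control, Irf7 was lowest at 2.62 FPKM in 39 (next 2.87), and Bcat1 was highest at 12.7 in 41 (7.10), Scnn1b at 21.4 in 37 (19.8) and Snord37 at 2.06 in 39 (1.10).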

How the results depend on the processing

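Limma voom and leaving out both libraries that stand apart were chosen after the results were seen, and the other alternatives before. Between Ctr shRNA and control the 994 genes became 597 without a filter on low values and 2087 with sample weights, and 456 to 1264 with each library left out, at 487, 477, 456 and 659 without control 37, 38, 39 and Ctr shRNA 4. Between the shRNA groups the 0 genes became 1, Cyp24a1, at a pseudocount of 0.1, at a mean FPKM of 5 or more, with only 2 groups fitted and with voom, and 0 to 3 with each library left out. Between the libraries labelled Gcgr shRNA and control the 268 genes became 155 without a filter, 154 at a mean FPKM of 5 or more, 1070 with sample weights, 438 with only 2 groups fitted, and 103 to 348 with each library left out, at 131, 105, 103, 165 and 170 without control 37, 38, 39, Gcgr shRNA 13 and Gcgr shRNA 35. The share higher was 70.5%, and 54.1% after rescaling to the same total. Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons where the preset called 19, 12 and 17, and fry called 16, 0 and 11. Leaving out each library gave 18 to 21, 9 to 16 and 16 to 19 lists. Leaving out both libraries that stand apart gave 1085, 0 and 284 genes and 20, 11 and 16 lists, kept 4 of the 12 list calls between the shRNA groups, and turned the median of mitochondrially encoded genes between the shRNA groups to -0.048. The difference in Gcgr kept its side throughout, from -1.10 to -0.92 for Ctr shRNA against control and from 0.28 to 0.46 between the shRNA groups with each library left out. The correlation of fold changes moved from -0.551 to -0.197 with Ctr shRNA in separate sets of 3, by construction without its shared libraries, and stayed between -0.626 and -0.501 with each library left out. For the other changes the cause was not tested. No paired analysis was possible because the groups share no replicate numbers.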

Other observations

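The list of p53 targets and all tests of it here were chosen after the result was seen. Targets of p53, the transcription factor that answers DNA damage and other stress, were higher in both shRNA groups than in control. Of 34 tested, 19 rose in Ctr shRNA and 18 in the libraries labelled Gcgr shRNA, and the same 18 rose in both, with median log2 fold changes of 0.56 and 0.49. Besides Cdkn1a, Phlda3 and Gdf15 they included Plk2, a stress kinase (1.03 and 1.03), Bbc3, which promotes cell death (1.01 and 0.85), Zmat3, an RNA-binding protein (0.65 and 0.63), Mdm2, which degrades p53 (0.47 and 0.50), and the receptor Eda2r (1.08 and 1.16). As Cdkn1a, Phlda3, Gdf15 and Btg2 were seen among the named genes before the list was made, the list was tested again without them. Of the 30 others 15 and 14 rose, with medians of 0.42 and 0.42, and camera with an estimated correlation gave an unadjusted p of 0.000427 and 3.56e-05. The comparisons share the controls, and 14 of these 30 rose in both. With the controls split into 2 and 2, a mean of 6.17 did (from 4 to 7). The split fits called fewer genes of any kind higher, means of 109 and 36.2 against 475 and 189, so these counts are not alike. In each of 100 draws of unchanged groups 0 rose in both. Such draws called almost no gene at all, so this 0 does not measure what shared controls create. Between the shRNA groups 0 of the 30 passed limma's test, and camera gave an unadjusted p of 0.279 with the preset correlation and 0.446 with an estimated one.

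Scaling does not account for these rises, as the lowest median over 4 scalings and both groups was 0.46. The shared genes lie on 13 chromosomes, so they are not neighbours in 1 linked segment. The list itself is spread over many chromosomes, so this cannot exclude a segment that holds a regulator of these genes. The hypothesis that p53 is more active in kidneys carrying the disease label may hold, but disease and any hairpin or vehicle both separate these groups from control, and a difference in processing between them was not tested. Wild-type kidneys given the same hairpin or vehicle, and diseased kidneys without any hairpin, would tell these apart. Cell type markers also moved in both comparisons, with medians of 0.48 and 0.54 for macrophage and -0.40 and -0.30 for proximal tubule markers. Whether cell content bears on the p53 targets was not tested.

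Whether Gcgr was knocked down in proximal tubule cells stays open, and no reduction appears between the shRNA groups once segment markers are subtracted (0.024 with thick ascending limb markers, exact permutation p = 0.763, and 0.26 with proximal tubule markers, exact permutation p = 0.0192). Gcgr counted in sorted proximal tubule cells would test such a knockdown. A measure of the hairpin in each sample could tell whether labels were exchanged (0.40 as labelled), but not whether Gcgr fell. Cyp24a1 may respond to the hairpin against Gcgr, with an adjusted p of 0.000946 when only the shRNA groups were fitted and 0.209 at the other end of its alternatives. Its level by PCR in further animals of both shRNA groups would test this.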
